A study of Caenorhabditis elegans with 15 samples.

How the data were processed

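RNA was measured in C. elegans in 15 libraries that the labels place in 9 groups. Small RNA, poly(A)-selected RNA and rRNA-depleted RNA were each sequenced from young adults of the wild type N2 and of the emb-4(hc60) mutant, with 2 libraries per group. Worms were kept at 14 °C and moved to 20 °C for a generation, per the labels' protocols. The EMB-4 immunoprecipitate, a mock precipitate made without antibody and the input were sequenced from gravid wild-type adults, with 1 library each, pooled from 4 precipitations per the labels. Both mRNA library types were made from the same treated RNA according to the labels' protocols, so they are not independent evidence. The labels do not say that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples.

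The submitters' processing notes name cutadapt 1.10, Bowtie2, STAR 2.3.0e, featureCounts 1.5.1, bedtools 2.25.0, DESeq2 and the genome build ce10, with no roles or order. The strand used for counting, the treatment of reads with several matches and the classes of small RNA read that were counted are not given in the sources used here. Reads of near-identical copies, such as histone and major sperm protein genes, and of overlapping or antisense genes are therefore uncertain. The deposited mRNA values are a normalised signal: every value was a whole multiple of what 1 read was worth in its library, to a tolerance of 0.05 for 100% of values, so read counts could be recovered. The authors' scaling of the mRNA signal gave the same factors as the median-ratio method. The deposited small RNA values are RPM, reads scaled to a library total, and 100% of them came out as whole reads. The deposited immunoprecipitation values are FPKM for exons, introns and gene bodies. The column names of the poly(A) libraries carry processing tags that the rRNA-depleted ones lack, so levels in both library types were not treated as measured alike.

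Names came from a WBcel235 gene table, which was not the build of the files and was used only for names, for which genes neighbour each other and for intron lengths as a gene property. It matched 17368 of 17669 mRNA identifiers, 19879 of 20389 small RNA identifiers and 19360 of 19802 immunoprecipitation identifiers. All columns of per-sample values were used.

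Reads in genes numbered 7635795 to 14309506 per poly(A) library and 2093383 to 3338419 per rRNA-depleted library. Small RNA reads in genes numbered 11338478 and 802207 in the mutant and 675247 and 6366022 in the wild type, and the RPM steps implied totals of 22121247, 1512635, 1051505 and 9355454 reads. For the immunoprecipitation libraries, whole reads were recovered from FPKM with a depth scale of 3147051 for the input, 11117635 for the mock and 19007963 for the EMB-4 precipitate. Of 18345 genes with recovered reads, 16842 (91.8%) had exon and intron reads that added up to the gene-body reads within 5% and were used. On simulated data, 96.1% of 3910 genes had every count right.

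The tests were fixed before the data were examined for whole-number counts and edgeR's quasi-likelihood test. Because the files held normalised values, the main test became limma 3.58.1 (trend and robust options, R 4.3.3) on log2 of the value plus a pseudocount of 2 (mRNA) or 1 (small RNA), and edgeR 4.0.16 on the recovered reads became an added alternative. A log2 change on this scale understates the change of low genes. A gene was tested if at least 2 libraries reached a normalised count of 10 or 5 RPM. The 8 mRNA libraries shared a single fit with group means and no block, from which both genotype differences and their interaction were taken. The 4 small RNA libraries had their own fit. A gene was called at a Benjamini-Hochberg adjusted p below 0.05.

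Gene lists were 26 lists of C. elegans genes written before the data were examined, covering small RNA pathways, germline, spliceosome, somatic tissues, stress, immunity, sex determination and gene families. Added to these were quintiles of wild-type small RNA level among genes of at least 1 RPM, the top quintile divided at the median wild-type mRNA level, and the list of genes with raised intron reads in the EMB-4 precipitate. These added classes came from the same samples. The quintiles were therefore tested only in mRNA. The small RNA change of both top-quintile classes bears a selection on wild-type level that their contrast may not fully remove. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Lists with fewer than 3 tested members were not tested: this applied to the mitochondrial genome, with 0 genes matched, and to microRNAs, with 0 genes tested in mRNA and 1 in small RNA. On simulated poly(A) data a list of genes raised 2-fold was called and 0 of the random lists were. Genes were drawn independently of each other there, so this does not test the preset correlation.

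The rule for named genes was also set before the data were examined. It took emb-4, up to 8 called genes with the largest rise and up to 8 with the largest fall among those with a mean CPM of at least 10 and both mutant libraries on the same side of both wild-type libraries, and up to 3 members with the smallest p of each list described. For the immunoprecipitation it took up to 10 listed genes with the highest lower bound of the ratio to the mock. On simulated libraries with known changes, 4-fold rises were called for 94% of changed genes in poly(A) RNA, 92% in rRNA-depleted RNA and 100% in small RNA, 2-fold rises for 40.4%, 57.4% and 58%, and 2-fold falls for 30.2%, 46.5% and 55.1%. Far fewer genes were changed in the simulation than were called in the data, which makes the adjusted p stricter. These rates therefore do not carry over, and the share of 2-fold changes missed in the data was not measured. Unchanged genes called in the simulation numbered 2, 23 and 4, and 0 for the interaction. The shared fit thus made more false calls in rRNA-depleted than in poly(A) RNA.

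Intron reads were compared as shares of gene-body reads with exact binomial 95% intervals, and per gene as ratios of intron reads scaled to all gene-body reads with exact conditional binomial intervals. Intervals cover counting error only. The list of genes with raised intron reads took genes with at least 30 intron reads over the 3 libraries and ratios of at least 2 to both the mock and the input. A ratio against 0 reads was computed against 3 reads. List medians were placed among 10000 random lists of the same size matched on mean level.

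Alternatives planned ahead were other scalings (median ratio and library total), no filter and a stricter filter at a mean CPM of 5, DESeq2 1.42.0 on the recovered reads, a log2 change of at least 1, the replicate number as a block, leaving out each library in turn, a fit of each mRNA library type alone, and other limits for the immunoprecipitation lists. Added after the data were seen were edgeR, TMM scaling, smaller and larger pseudocounts, list tests under other scalings and without each library, correlations under TMM or without each library, and the intron share over all recovered genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the immunoprecipitation and the figures.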

Results

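The data covered the small RNA and messenger RNA of C. elegans worms mutant for emb-4, which the series title describes as encoding a conserved intron-binding protein, and the RNA bound by EMB-4 in wild-type worms. Small RNA, poly(A)-selected RNA and rRNA-depleted RNA were sequenced from wild-type and emb-4(hc60) young adults with n = 2 libraries per group. The EMB-4 immunoprecipitate, a mock precipitate and their input had 1 library each. Reads in genes ranged from 7635795 to 14309506 per poly(A) library, from 2093383 to 3338419 per rRNA-depleted library and from 675247 to 11338478 per small RNA library. Spearman correlations between replicates across genes ranged from 0.957 (small RNA, wild type) to 0.995 (poly(A), wild type), and the replicate counts differed by more than sampling noise in all 6 pairs (chi-square per degree of freedom 1.29 to 8.76). Values below are normalised read counts for mRNA or RPM (reads scaled to the library total) for small RNA, as mean ± SD of 2 libraries, and changes are mutant minus wild type on the log2 scale.

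The mutated gene itself was read in every library. In poly(A) RNA, emb-4 stood at 189 ± 35.3 in the mutant and 372 ± 6.91 in the wild type, a log2 change of -0.98 (SE 0.17, limma adjusted p = 4.16e-04). In rRNA-depleted RNA it stood at 385 ± 41.6 and 726 ± 127, a change of -0.91 (SE 0.17, limma adjusted p = 6.45e-04). Small RNA reads of emb-4 stood at 34.6 ± 1.28 RPM in the mutant and 101 ± 7.22 RPM in the wild type, a change of -1.52 (SE 0.17, limma adjusted p = 9.85e-06). All 6 mutant libraries were below the wild-type libraries of their type. The labels do not describe the lesion of hc60, so a remaining transcript neither supports nor opposes the genotype labels.

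**Figure D1:**
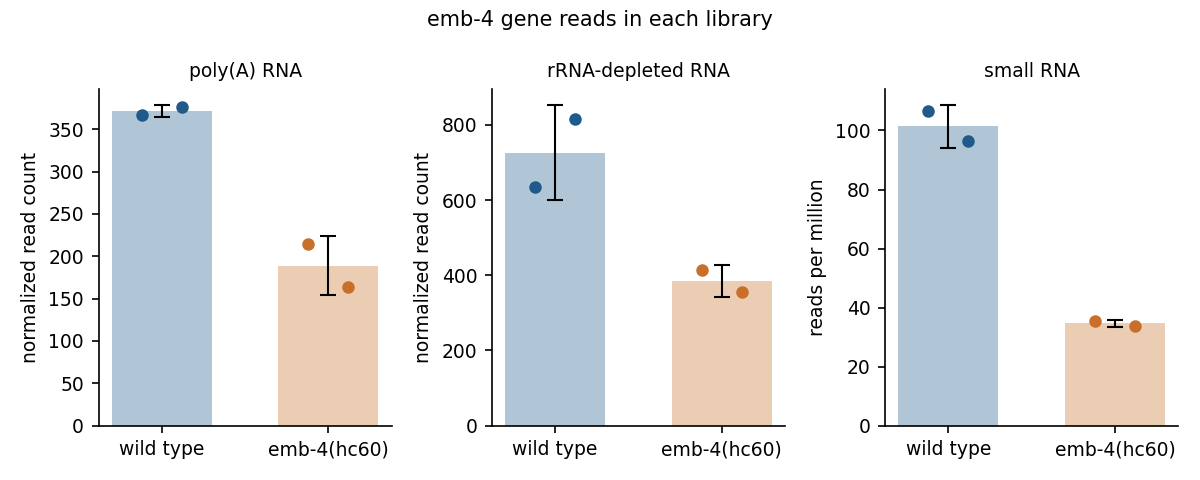
Reads of the emb-4 gene in poly(A), rRNA-depleted and small RNA libraries, in normalised read counts or RPM. Bars show the mean, error bars the SD and points the 2 libraries of each group, and the mutant lay below the wild type in all 3 library types.

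The poly(A) comparison asked which messenger RNAs differed between mutant and wild-type young adults. Genes of the female germline were lower in the mutant: oocyte and maternal genes, which supply the egg and early embryo, fell in 26 of 29 measured members (27 when adjusted over the list alone), and 3 did not pass. Among them, egg-1, an oocyte surface protein needed for fertilisation, fell from 1658 ± 86.9 to 406 ± 13.8, and chs-1, the eggshell chitin synthase, from 1158 ± 40.3 to 240 ± 19.8. Meiosis and germline stem cell genes fell in 35 of 36 members (35 adjusted over the list alone). The translational repressor gld-1 fell from 1759 ± 56 to 339 ± 56 and the synaptonemal complex gene syp-4 from 278 ± 13.6 to 69.4 ± 6.26. P granule and germ granule genes, coding for components of the perinuclear RNA granules of germ cells, fell in 20 of 21 members (20 adjusted over the list alone), including cgh-1, a DEAD-box helicase, from 5324 ± 288 to 1250.0 ± 181, and meg-1 from 376 ± 30.8 to 83.6 ± 3.8. The median log2 changes of these 3 lists were -1.74, -1.50 and -1.65, with camera adjusted p = 3.92e-12, 3.88e-13 and 1.17e-09. With an estimated correlation the adjusted p were 0.173, 0.1 and 0.152, so the 3 calls were lost.

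Male germline genes moved less. Spermatogenesis genes fell in 6 of 29 members and rose in 1 (5 and 1 adjusted over the list alone), with 22 not passing. The RNA-binding protein gene cpb-1 fell from 108 ± 18.6 to 21.01 ± 6.22 and spe-5 from 61.6 ± 2.45 to 15.8 ± 1.9, while swm-1, a protease inhibitor that holds back sperm activation, rose from 188 ± 25.2 to 421 ± 20.1. The list had a median of -0.44 (camera adjusted p = 0.0391, and adjusted p = 0.152 with an estimated correlation). The call ended without mutant replicate 1 (adjusted p = 0.0838) or wild-type replicate 1 (0.075) and under library totals (0.056). With the main scaling none of the 27 major sperm protein genes passed in limma, with 0 called over all genes and 0 adjusted over the list alone. Their median was -0.03 (camera adjusted p = 0.837), moving to 0.02 under TMM and -0.54 under library totals. Under library totals msp-50 (-0.83, limma adjusted p = 0.00181), msp-64 (-0.84, 0.00183) and msp-49 (-0.86, 0.00943) passed as lower. Sex determination genes fell in 10 of 17 members and rose in 1 (the same numbers adjusted over the list alone, median -0.70, camera adjusted p = 0.00551). Their adjusted p was 0.173 with an estimated correlation. The masculinising gene fem-3 fell from 208 ± 9.33 to 44.5 ± 5.66. The list shares gld-1 and nos-3 with the meiosis and germline stem cell list, fog-1 and fog-3 with spermatogenesis, and mog-1, mog-4 and mog-5 with the spliceosome list.

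Genes of the small RNA pathways and of splicing were also lower, in lists that overlap each other and the P granule list. Argonautes share hrde-1 and nrde-3 with nuclear RNAi and csr-1, prg-1 and wago-1 with P granule genes. The gene rde-12 is in both the P granule and the small RNA biogenesis list. Small RNA biogenesis genes fell in 27 of 30 members (28 adjusted over the list alone, median -0.98, camera adjusted p = 5.71e-08). Their adjusted p was 0.152 with an estimated correlation. The RNA-dependent RNA polymerase gene ego-1 fell from 318 ± 8.33 to 92.0 ± 8.58 and the mutator gene mut-7 from 265 ± 3.47 to 92.5 ± 7.14. Argonaute genes, which code for the proteins that carry small RNAs, fell in 13 of 22 members and rose in 1 (14 and 1 adjusted over the list alone). Examples were the Piwi gene prg-2, from 345 ± 13.3 to 55.2 ± 10.6, and wago-2, from 133 ± 4.97 to 22.5 ± 3.25, and the microRNA Argonaute gene alg-5 fell by 2.17. The Argonaute median was -0.67 (camera adjusted p = 8.54e-04, and adjusted p = 0.287 with an estimated correlation). Genes of nuclear RNAi and histone H3 methylation fell in 15 of 19 members (15 adjusted over the list alone, median -0.98, camera adjusted p = 2.21e-04), and their adjusted p was 0.152 with an estimated correlation. The germline nuclear Argonaute gene hrde-1 fell from 1081 ± 3.59 to 328 ± 59.8 and the histone methyltransferase gene met-2 from 331 ± 9.25 to 137 ± 7.75. Spliceosome genes fell in 31 of 40 members (32 adjusted over the list alone, median -0.72, camera adjusted p = 3.66e-07, adjusted p = 0.152 with an estimated correlation), among them prp-4, from 146 ± 21.2 to 48.8 ± 3.67, and the helicase gene ddx-23 (-1.21).

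Genes of somatic tissues were higher in the mutant. Collagens, the cuticle proteins, rose in 94 of 130 members and fell in 8 (95 and 9 adjusted over the list alone), with col-40 at 1859 ± 111 against 188 ± 14.3 and col-2 raised by 3.29. All 6 vitellogenins, the yolk proteins made in the intestine, rose (6 adjusted over the list alone), and vit-2 stood at 267800 ± 5580 against 80980 ± 7650. The list medians were 1.19 and 1.00 (camera adjusted p = 2.44e-15 and 0.00339). With an estimated correlation these had adjusted p = 0.152 and 0.297. Muscle genes rose in 21 of 35 members and fell in 2 (the same adjusted over the list alone, median 0.69, camera adjusted p = 4.16e-05, adjusted p = 0.182 with an estimated correlation), and the muscle myosin gene unc-54 stood at 10560 ± 138 against 3111 ± 342. Neuron genes rose in 17 of 25 and fell in 1 (the same adjusted over the list alone, median 0.86, camera adjusted p = 1.44e-05, adjusted p = 0.1 with an estimated correlation), with the neuropeptide gene flp-14 at 188 ± 15.5 against 65.2 ± 1.38. Intestine genes rose in 20 of 29 members and fell in 4 (20 and 5 adjusted over the list alone, median 0.91, camera adjusted p = 2.13e-04, adjusted p = 0.218 with an estimated correlation). The metallothionein gene mtl-1 stood at 6508 ± 287 against 319 ± 10.7 and the ferritin gene ftn-1 at 1969 ± 79.6 against 454 ± 44.6.

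Ribosomal protein genes rose in 67 of 74 members and fell in 1 (71 and 1 adjusted over the list alone, median 0.67, camera adjusted p = 3.34e-11, adjusted p = 0.286 with an estimated correlation), with rpl-11.2 at 8743 ± 1210 against 3103 ± 244. Histone genes rose in 26 of 69 members and fell in 2 (25 and 2 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 0.0014, and adjusted p = 0.467 with an estimated correlation). The variant histone gene his-71 stood at 691 ± 38.4 against 238 ± 14.2. Members of the pals family, which includes regulators of the response to intracellular pathogens, rose in 16 of 22 and fell in 1 (17 and 1 adjusted over the list alone, median 1.24, camera adjusted p = 9.9e-05, adjusted p = 0.218 with an estimated correlation), with pals-14 at 126 ± 1.22 against 20.7 ± 2.9. C-type lectins rose in 49 of 105 members and fell in 18 (49 and 19 adjusted over the list alone, camera adjusted p = 0.00155, adjusted p = 0.152 with an estimated correlation), and their median of 0.58 turned to -0.09 under library totals. Innate immune effectors rose in 12 of 31 members and fell in 7 (13 and 7 adjusted over the list alone, camera adjusted p = 0.0366, adjusted p = 0.216 with an estimated correlation), and their median of 0.30 turned to -0.23 under library totals, where the call ended (adjusted p = 0.113). The lectin gene clec-15 stood at 606 ± 13.1 against 50.2 ± 12.4 and the flavin monooxygenase gene fmo-2 at 117 ± 2.78 against 9.36 ± 3.84. Targets of ERGO-1 class small RNAs rose in 8 of 13 members with 0 falling (8 adjusted over the list alone, median 1.05, camera adjusted p = 0.0177), led by K02E2.6 at 120 ± 3.58 against 45.8 ± 15.2. Their adjusted p was 0.152 with an estimated correlation.

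Other lists that did not pass in poly(A) RNA, apart from major sperm proteins, held members that moved both ways. Heat shock and stress genes rose in 9 of 29 members and fell in 7 (9 and 6 adjusted over the list alone, camera adjusted p = 0.309), with the catalase gene ctl-2 at 3312 ± 59.5 against 1034 ± 52.2 and the mitochondrial chaperonin gene hsp-60 at 177 ± 17.8 against 500 ± 25.6. Their median of 0.19 turned to -0.23 under library totals. F-box A and B genes rose in 36 of 120 members and fell in 21 (35 and 20 adjusted over the list alone, camera adjusted p = 0.0817), and their median of 0.41 turned to -0.09 under library totals, where the list passed as higher than other genes (adjusted p = 0.0193). MATH and BATH genes rose in 6 of 38 members and fell in 15 (6 and 16 adjusted over the list alone, median -0.33, camera adjusted p = 0.11).

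The largest rises belonged to comt-4, of the catechol O-methyltransferase family, at 408 ± 4.81 against 2.01 ± 0.58 (log2 change 6.68, SE 0.26, limma adjusted p = 1e-08), W02D7.11 at 932 ± 24.7 against 8.01 ± 1.08 (6.55) and the arginine kinase gene argk-1 at 187 ± 3.03 against 3.90 ± 0.631 (5.01). These were followed by dao-6 (4.86), ZC250.4 (4.68), F26A3.4 (4.38), mtl-1 (4.34) and ZK355.8 (4.22). The largest falls belonged to drd-10, at 6.63 ± 1.86 against 386 ± 27.9 (-5.50, SE 0.3, limma adjusted p = 1.09e-07), Y39B6A.1 (-4.28), hrg-11.3 (-3.50) and pud-3 (-3.09), then the intestinal acid phosphatase gene pho-1 (-2.62), prg-2 (-2.61), srlf-34 (-2.58) and C33G8.2 (-2.51). In total 3251 genes rose and 3654 fell among 12231 tested, so 47.1% of calls were rises. Under library totals 1633 rose and 5611 fell (22.5% rises), because that scaling moved the median of all genes from -0.03 to -0.54. The direction of each list that passed was the same under TMM and library totals unless stated, and medians under library totals were lower, such as 0.16 for ribosomal protein genes, 0.03 for histones and 0.19 for muscle.

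**Figure D2:**
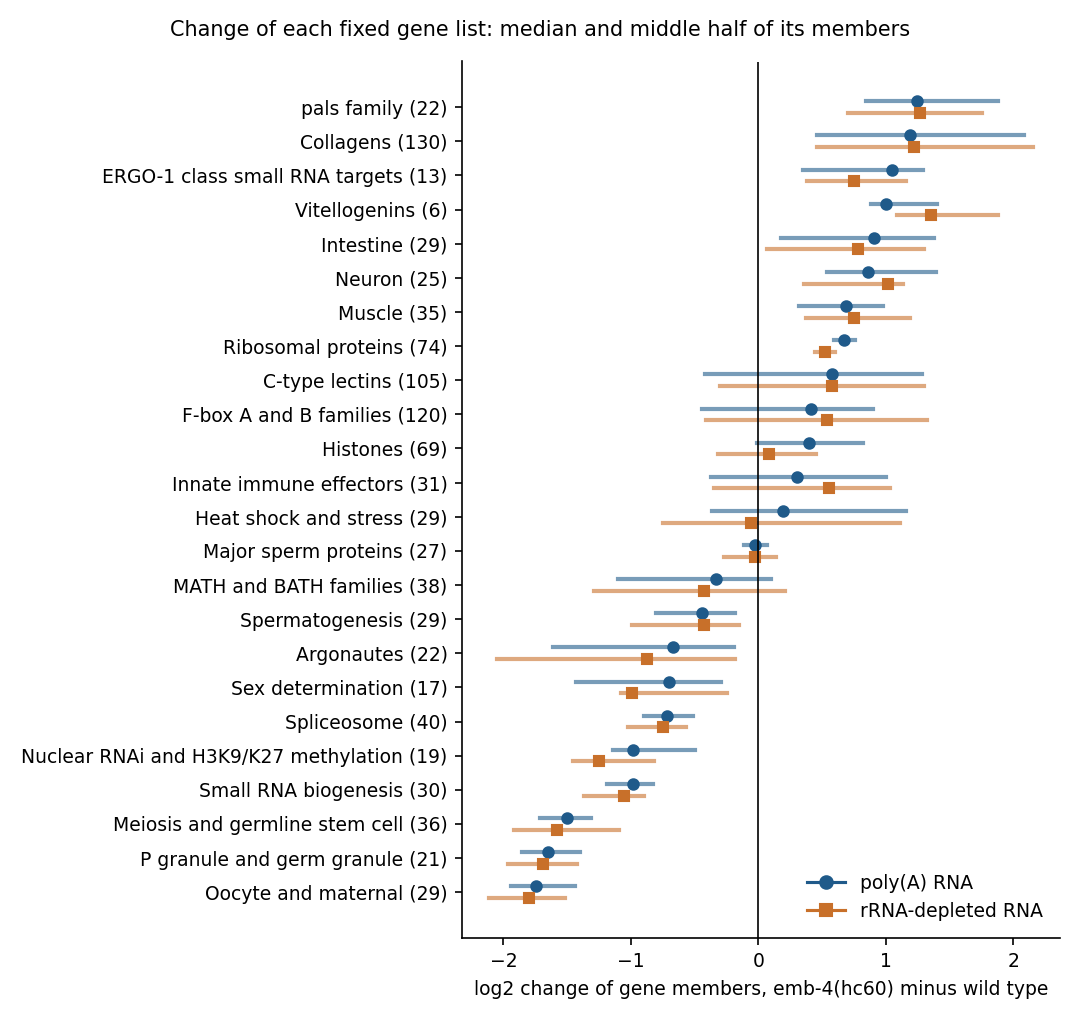
Median log2 change (mutant minus wild type) and middle 50% of members for each fixed gene list in poly(A) and rRNA-depleted RNA, with the number of members tested. Oocyte, P granule and meiosis lists lay lowest and pals, collagen and vitellogenin lists among the highest in both library types. Under library totals every list lay lower and some of the higher lists lay at or below 0.

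Genes were next ordered by their small RNA level in wild-type worms, to ask whether mRNA changes went with the small RNAs of a gene. In the lowest quintile 602 of 1433 genes rose and 84 fell (median 0.57, camera adjusted p = 1.77e-09), and in the next 517 of 1713 rose and 224 fell (median 0.22, turning to -0.29 under library totals, camera adjusted p = 0.00243). Both calls held with an estimated correlation (adjusted p = 0.00806 for each), the only 2 in this comparison that did. In the middle quintile 394 of 2113 rose and 683 fell (median -0.23, camera adjusted p = 0.0615), and under library totals the class passed as lower than other genes (adjusted p = 0.0184). The upper quintiles held 294 rises and 1286 falls among 2344 genes (median -0.59, camera adjusted p = 3.01e-11) and 247 rises and 1219 falls among 2138 (median -0.65, camera adjusted p = 2.7e-12). With an estimated correlation these had adjusted p = 0.1 and 0.152. Inside the top quintile, genes with high wild-type mRNA fell in 1169 of 1790 cases and rose in 156 (median -0.76, camera adjusted p = 9.35e-18, adjusted p = 0.152 with an estimated correlation). Genes with low mRNA rose in 89 of 346 and fell in 50 (median 0.19, camera adjusted p = 0.0648). Library totals moved all genes down and this median to -0.29, and there the class passed as higher than other genes (adjusted p = 0.0063). These classes were drawn from wild-type levels in this study and are not independent of it. They also go with tissue: 27 of 29 oocyte and 36 of 37 meiosis genes passed the small RNA filter, but 14 of 35 muscle and 6 of 31 intestine genes. A link with small RNA level and a lower germline share therefore cannot be told apart. Of 644 low-mRNA genes only 346 were tested. A gene low in the wild type can pass the filter through the mutant libraries, which favours rises in that class.

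**Figure D3:**
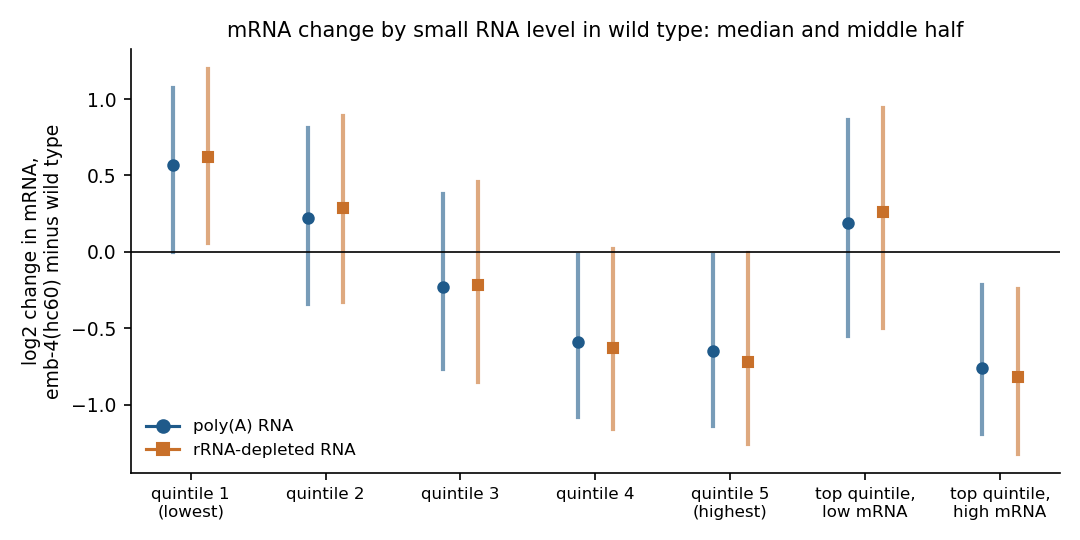
Median log2 mRNA change and middle 50% of genes in quintiles of wild-type small RNA level and in the low-mRNA and high-mRNA parts of the top quintile, for both mRNA library types. The poly(A) median went from 0.57 in the lowest quintile to -0.65 in the highest, and the medians of quintile 2 and of the low-mRNA part turned negative under library totals. Small RNA level was not separated from germline expression.

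The rRNA-depleted comparison asked the same question without selection by poly(A) tail. Among members of the fixed lists, egg-2 fell from 807 ± 120 to 124 ± 28.5, the yolk receptor gene rme-2 from 3310.0 ± 475 to 672 ± 114 and the germline Notch receptor gene glp-1 from 954 ± 183 to 193 ± 57.6. The P granule gene pgl-1 fell from 1037 ± 32.7 to 270.1 ± 48, the Piwi gene prg-1 from 982 ± 150 to 316 ± 1.35, the Argonaute gene wago-4 from 642 ± 113 to 138 ± 36.6 and the small RNA biogenesis gene rde-3 from 271 ± 8.19 to 50.1 ± 0.968. In the other direction, vit-2 rose from 70330 ± 13900 to 325600 ± 26800 and unc-54 from 6348 ± 457 to 25490 ± 819, and the collagen gene col-40 rose by 3.12. The largest rises were W02D7.11 (6.14), comt-4 (5.48), B0024.4 (4.90), mtl-1 (4.49), Y60C6A.1 (4.47), ZK355.8 (4.44), argk-1 (4.39) and F26A3.4 (4.20). The largest falls were drd-10 (-5.38), F59B2.12 (-5.11), hrg-11.3 (-4.48), Y39B6A.1 (-3.76), F55G1.6 (-3.02), pud-3 (-2.84), T28A8.4 (-2.82) and C50E3.13 (-2.77). Of 12231 genes, 3617 rose and 3847 fell (limma, 48.5% rises), and under library totals 1887 rose and 5584 fell (25.3% rises, median of all genes -0.51 against 0.01).

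By list, oocyte genes fell in 25 of 29 members (25 adjusted over the list alone, median -1.80, camera adjusted p = 3.58e-11), meiosis genes in 34 of 36 (34, -1.58, 4.2e-12), P granule genes in 21 of 21 (21, -1.69, 2.03e-09) and small RNA biogenesis genes in 29 of 30 (29, -1.05, 9.63e-09). For these 4 lists, adjusted p = 0.175, 0.147, 0.169 and 0.156 with an estimated correlation. Nuclear RNAi genes fell in 17 of 19 members and rose in 1 (17 and 1 adjusted over the list alone, median -1.25, camera adjusted p = 9.02e-06), spliceosome genes fell in 33 of 40 (34, -0.75, 1.84e-07), Argonaute genes fell in 14 of 22 and rose in 2 (14 and 2, -0.87, 6.16e-04) and sex determination genes fell in 10 of 17 (10, -0.99, 0.00349). For these, adjusted p = 0.156, 0.156, 0.275 and 0.175 with an estimated correlation. Collagens rose in 95 of 130 members and fell in 6 (98 and 7 adjusted over the list alone, median 1.22, camera adjusted p = 1.32e-14), vitellogenins rose in 6 of 6 (6, 1.35, 0.00153), and muscle genes rose in 24 of 35 and fell in 2 (24 and 2, 0.75, 1.68e-05). For these, adjusted p = 0.169, 0.275 and 0.175 with an estimated correlation. Neuron genes rose in 17 of 25 members and fell in 1 (the same adjusted over the list alone, median 1.02, camera adjusted p = 2.62e-04), intestine genes rose in 19 of 29 and fell in 4 (20 and 4, 0.78, 5.6e-04) and pals genes rose in 16 of 22 and fell in 1 (16 and 1, 1.27, 1.22e-04). For these, adjusted p = 0.156, 0.25 and 0.229 with an estimated correlation.

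Ribosomal protein genes rose in 55 of 74 members and fell in 1 (56 and 1 adjusted over the list alone, camera adjusted p = 1.96e-07, adjusted p = 0.368 with an estimated correlation), and their median of 0.52 became 0.00 under library totals. C-type lectins rose in 53 of 105 members and fell in 17 (53 and 17 adjusted over the list alone, camera adjusted p = 7.43e-04, adjusted p = 0.156 with an estimated correlation), and their median of 0.58 turned to -0.01 under library totals. Innate immune effectors rose in 17 of 31 members and fell in 8 (18 and 8 adjusted over the list alone, median 0.55, camera adjusted p = 0.0389, adjusted p = 0.221 with an estimated correlation), and the call ended without mutant replicate 2 (adjusted p = 0.0803) and under library totals (0.0954). ERGO-1 class targets rose in 7 of 13 members and fell in 1 (7 and 1 adjusted over the list alone, median 0.75, camera adjusted p = 0.0389, adjusted p = 0.175 with an estimated correlation), and the call ended without mutant replicate 1 (0.0516) or wild-type replicate 2 (0.0872). F-box genes rose in 51 of 120 members and fell in 18 (50 and 18 adjusted over the list alone, median 0.54, camera adjusted p = 0.0128, adjusted p = 0.351 with an estimated correlation), and the call ended without wild-type replicate 2 (0.11). Lists that did not pass were spermatogenesis (8 falls and 1 rise among 29, median -0.43, camera adjusted p = 0.0564), histones (13 rises and 14 falls among 69, median 0.08, turning to -0.44 under library totals, mean -0.10, 0.948), heat shock (11 rises and 7 falls among 29, median -0.06 but mean 0.22, 0.628), MATH and BATH (6 rises and 15 falls among 38, median -0.43, 0.143) and major sperm proteins (1 rise and 3 falls among 27, median -0.03, 0.846). Adjusted over the list alone, falls and rises numbered 8 and 1, 14 and 10, 7 and 11, 15 and 6, and 0 and 0 in these lists. With 1 library left out the lowest adjusted p were 0.0437 for spermatogenesis and 0.0455 for major sperm proteins.

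By small RNA level, the lowest wild-type quintile rose in 694 of 1433 genes and fell in 94 (median 0.62, camera adjusted p = 4.4e-10, adjusted p = 0.00687 with an estimated correlation), and the highest fell in 1283 of 2138 and rose in 288 (median -0.72, camera adjusted p = 3.71e-13, adjusted p = 0.169 with an estimated correlation). Quintile 2 rose in 583 and fell in 243 (median 0.29, turning to -0.23 under library totals, camera adjusted p = 0.00153, adjusted p = 0.00687 with an estimated correlation), quintile 3 did not pass (435 and 731, median -0.22, 0.0759) and quintile 4 fell in 1345 and rose in 298 (median -0.63, camera adjusted p = 6.22e-12, adjusted p = 0.144 with an estimated correlation). In the top quintile, high-mRNA genes fell in 1238 of 1842 cases and rose in 209 (median -0.82, camera adjusted p = 1.15e-17, adjusted p = 0.169 with an estimated correlation), and low-mRNA genes rose in 79 of 295 and fell in 44 (median 0.26, turning to -0.20 under library totals, camera adjusted p = 0.115). Under library totals quintile 3 passed as lower than other genes (camera adjusted p = 0.0207) and the low-mRNA genes as higher (0.0122). Only 295 of 653 low-mRNA genes were tested, with the same filter that favours rises.

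Changes in both mRNA library types were then compared, and genes are not independent replicates in such a comparison. Across 12231 genes the log2 changes had a Spearman correlation of 0.91 and a Pearson correlation of 0.91. There were 2794 genes that rose in both and 3246 that fell in both, where independent lists would share 961 and 1149, and 7 and 3 genes were called in opposite directions. The genotype difference itself differed between library types for 12 genes, 3 higher and 9 lower in rRNA-depleted RNA (limma, 654 at an unadjusted p below 0.05). Of the 12, 8 were histone genes. Replication-dependent histone messages lack a poly(A) tail, and his-14 stood at 161 ± 38.8 in the mutant and 763 ± 130 in the wild type in rRNA-depleted RNA but at 18.8 ± 4.04 and 5.53 ± 1.06 in poly(A) RNA. Likewise his-10 stood at 155 ± 3.81 and 676 ± 39.2 against 14.9 ± 4.41 and 5.61 ± 1.1. Most histone genes did not share this fall, and the median of the histone list in rRNA-depleted RNA was 0.08. The other 4 were acs-2, coding for an acyl-CoA synthetase, at 1097 ± 35.6 and 244 ± 57.1 in rRNA-depleted and 1795 ± 148 and 138 ± 10.5 in poly(A) RNA, and gfi-1, bcf-1 and Y16B4A.2, which were lower in the mutant in both types. Their changes were -0.51, -0.63 and -1.06 in rRNA-depleted RNA and -2.17, -2.06 and -2.44 in poly(A) RNA. Only his-14 and his-10 stayed called without each of the 8 libraries in turn (highest adjusted p = 0.0216 for both). For emb-4 the difference was 0.08 (limma adjusted p = 0.991).

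**Figure D4:**
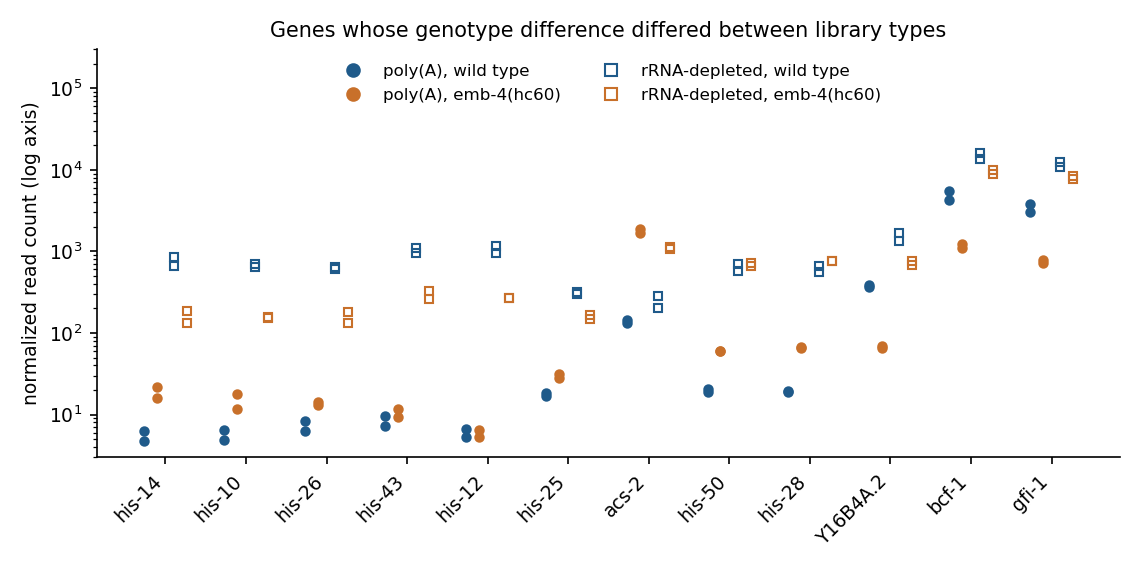
Normalised read counts (log axis) of the 12 genes whose genotype difference differed between library types, with 1 point per library. The histone genes his-14, his-10, his-26 and his-25 were lower in the mutant in rRNA-depleted RNA and higher in poly(A) RNA.

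As lists, histone genes had a lower change in rRNA-depleted than in poly(A) RNA, with 8 of 69 members lower (16 adjusted over the list alone, median difference -0.31, camera adjusted p = 3.4e-11, adjusted p = 0.935 with an estimated correlation), and fry did not call it (adjusted p = 0.717). Nuclear RNAi genes (-0.33, 0.0025), ribosomal protein genes (-0.15, 0.0025), the top small RNA quintile (-0.08, 0.0355), its high-mRNA part (-0.08, 0.0199) and F-box genes (0.22, 0.0157) also passed, with 0 members called over all genes and 1 nuclear RNAi gene, lower, adjusted over the list alone. With an estimated correlation the adjusted p were 0.834 for nuclear RNAi genes and 0.935 for the other 4 of these. The other tested lists did not pass (lowest camera adjusted p = 0.071, vitellogenins, which passed under TMM and library totals with 0.0486 and 0.01). Only the histone call held without each library in turn (highest adjusted p = 0.0152). The calls of ribosomal protein genes, F-box genes and both small RNA classes ended without rRNA-depleted wild-type replicate 2 (adjusted p = 0.835, 0.831, 0.452 and 0.514), and that of nuclear RNAi genes without rRNA-depleted mutant replicate 2 (0.142).

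The small RNA comparison asked for which genes the reads of small RNAs differed. Most called genes had fewer small RNA reads in the mutant: snrp-200, a spliceosomal helicase gene, stood at 336 ± 0.441 RPM against 1183 ± 103 RPM, the oocyte RNA-binding protein gene puf-3 at 41.4 ± 4.12 against 163 ± 1.62, the germ granule gene meg-4 at 7.61 ± 2.35 against 57 ± 4.12 and the Argonaute gene wago-1 at 31.6 ± 1.64 against 113 ± 7.23. The largest falls were Y110A2AL.1, at 18.3 ± 0.239 against 593 ± 143 RPM (-4.92, SE 0.19, limma adjusted p = 9.07e-10), intk-1 (-4.85), Y7A5A.8 (-4.38), caap-1 (-3.89), iff-1 (-3.82), rpb-11 (-3.65), rps-16 (-3.65) and gtf-2F2 (-3.59). With edgeR, caap-1 and iff-1 did not pass (adjusted p = 0.133 and 0.0698). The largest rises were Y55D5A.1, at 72.6 ± 5.83 against 1.699 ± 0.287 RPM (4.77, SE 0.27, limma adjusted p = 7.17e-08), B0261.8 (4.31), F21D5.4 (3.72), Y53G8AL.4 (3.68), the zinc finger gene ztf-31 (3.61), T08B2.3 (3.45), F08G5.3 (3.42) and Y55D5A.4 (3.35). F21D5.4 did not pass without 2 of the 4 libraries (highest adjusted p = 0.148). Of 8538 genes, 778 rose and 4648 fell (14.3% rises). Rises numbered 339 and 314 without mutant replicate 1 and 2, and 712 and 1181 without wild-type replicate 1 and 2.

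This split depended on scaling. The median of all genes was -0.69 with the deposited RPM, -0.35 with library totals in genes, -0.07 with median-ratio factors and -0.02 with TMM, where rises and falls numbered 1285 and 3150 (29% rises), 1833 and 1834 (50.0%) and 1856 and 1552 (54.5%). Gene RPM summed to 512561 and 530337 in the mutant libraries and to 642172 and 680461 in the wild type. The list changes below are therefore read against the median of all genes, as camera does.

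Against that median, oocyte genes lost more small RNA than others: 27 of 27 fell (27 adjusted over the list alone, median -1.48, camera adjusted p = 3.18e-06, adjusted p = 0.59 with an estimated correlation). Ribosomal protein genes fell in 58 of 64 members (58 adjusted over the list alone, median -1.54, camera adjusted p = 3.86e-05, adjusted p = 0.59 with an estimated correlation), among them rps-16 at 4.10 ± 2.06 against 62.6 ± 24.4 RPM and rpl-3 at 8.87 ± 1.48 against 44.1 ± 10.3. The oocyte gene cpg-1, of the eggshell, stood at 34.3 ± 4.81 against 146 ± 12.8. Spliceosome genes fell in 35 of 40 members (36 adjusted over the list alone, median -1.09, camera adjusted p = 2.16e-04), P granule genes in 18 of 21 (20, -1.09, 0.00347), nuclear RNAi genes in 17 of 19 (18, -0.89, 0.00733), and sex determination genes in 15 of 17 with 1 rise (15 and 1, -1, 0.0261). For these, adjusted p = 0.59, 0.612, 0.658 and 0.59 with an estimated correlation. The sex determination call ended without wild-type replicate 2 (adjusted p = 0.0617). The nuclear RNAi gene hrde-1 stood at 169 ± 16.6 against 439.9 ± 80.1 RPM, and mes-2, of the Polycomb-like complex, at 14.7 ± 4.02 against 60.5 ± 5.9.

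Some lists kept or gained small RNA against the median of all genes. Collagens rose in 6 of 19 members and fell in 2 (6 and 1 adjusted over the list alone, median 0.30, camera adjusted p = 3.86e-05, adjusted p = 0.59 with an estimated correlation), and neuron genes rose in 3 of 13 and fell in 2 (the same adjusted over the list alone, median 0.49, camera adjusted p = 1.93e-04, adjusted p = 0.59 with an estimated correlation), with unc-119 at 19.7 ± 1.07 against 6.92 ± 1.71 RPM. ERGO-1 class targets rose in 9 of 20 and fell in 5 (9 and 5 adjusted over the list alone, median 0.32, mean 0.02, camera adjusted p = 4.67e-04, adjusted p = 0.59 with an estimated correlation), and the call ended without wild-type replicate 1 (0.0747). The members with the smallest p went the other way: C18D4.6 stood at 143 ± 17.8 against 479 ± 47.8 RPM and fbxb-37 at 456 ± 14.9 against 1185 ± 131. F-box genes rose in 29 of 134 members and fell in 40 (29 and 38 adjusted over the list alone, camera adjusted p = 1.61e-04 as higher than other genes), and their median of -0.17 turned to 0.51 under TMM and 0.17 under library totals. Their adjusted p was 0.624 with an estimated correlation.

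Other lists did not pass in small RNA: Argonautes fell in 13 of 19 members (13 adjusted over the list alone, camera adjusted p = 0.202), small RNA biogenesis genes in 24 of 30 (25, 0.0622), meiosis genes in 29 of 36 (29, 0.0574), major sperm proteins in 19 of 25 (21, 0.202) and vitellogenins in 3 of 5 (3, 0.949). Histones fell in 28 of 67 members (27 adjusted over the list alone, camera adjusted p = 0.491), with a median of -0.61 that became 0.01 under TMM. Spermatogenesis genes fell in 8 of 23 and rose in 4 (6 and 3 adjusted over the list alone, 0.202), muscle genes fell in 4 of 14 and rose in 1 (2 and 0, 0.203), C-type lectins fell in 9 of 32 and rose in 4 (8 and 3, 0.0749), and MATH and BATH genes fell in 19 of 42 and rose in 5 (19 and 5, 0.202). With a block for replicate number meiosis genes had adjusted p = 0.0462, and the lowest adjusted p of lectins with 1 library left out was 0.0227. The medians of spermatogenesis, muscle, lectin and MATH and BATH genes, -0.42, -0.13, -0.26 and -0.22, turned to 0.20, 0.54, 0.37 and 0.48 under TMM, and camera placed all 4 above other genes. Heat shock genes fell in 9 of 15 and rose in 1 (9 and 1 adjusted over the list alone, 0.49), innate effectors fell in 4 of 7 (4, 0.794), intestine genes in 2 of 6 (2, 0.49) and pals genes in 2 of 7 (2, 0.567). The last 2 had medians of -0.23 and -0.32, which turned to 0.38 and 0.33 under TMM, and lay above other genes by camera.

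Genes of the top wild-type small RNA quintile divided by their mRNA level. Those with high mRNA fell in 1510 of 1842 cases and rose in 83 (median -1.01, camera adjusted p = 8.57e-14), and those with low mRNA fell in 240 of 653 and rose in 146 (median -0.14, turning to 0.54 under TMM, camera adjusted p = 3.8e-05 as higher than other genes). With an estimated correlation these had adjusted p = 0.59 and 0.663. The call of the low-mRNA class ended without wild-type replicate 1 (adjusted p = 0.0732). Both classes were chosen on wild-type levels in these libraries, so the contrast between them was compared, which may not remove that selection fully. It was -0.87 (95% bootstrap interval -0.931 to -0.788) with the deposited RPM and between -0.87 and -0.88 under the other 3 scalings. A scaling shifts both classes nearly alike, so that agreement was fixed in advance.

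Small RNA changes were then set against mRNA changes across 7077 genes, which are not independent replicates. The Spearman correlation was 0.215 with poly(A) RNA and 0.239 with rRNA-depleted RNA. There were 2397 genes with a fall in both small RNA and poly(A) RNA, against 1975 for independent lists, and 165 with a rise in both, against 66. Small RNA fell while poly(A) RNA rose for 462 genes against 656, and rose while poly(A) RNA fell for 45 against 199. With TMM, 764 genes fell in both against 632, and small RNA rose while poly(A) RNA fell for 182 against 485. The median small RNA change was -0.90 for 3250 genes lower in poly(A) RNA, -0.44 for 1079 genes higher and -0.70 for 2748 genes not called. Ribosomal protein genes, which rose in poly(A) RNA, were among those with fewer small RNAs.

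The immunoprecipitation asked which RNAs, and which parts of them, were bound by EMB-4. Each kind had a single library, so these values have no replicate check and no test, and they compare libraries, not conditions. Introns held 9.24% of gene-body reads in the EMB-4 precipitate (exact 95% interval 9.22 to 9.25), 3.21% in the mock (3.2 to 3.22) and 5.2% in the input (5.17 to 5.23). The ratio of shares was 2.88 to the mock and 1.78 to the input. It was 5.88 and 2.39 without the 10 genes with the most intron reads.

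**Figure D5:**
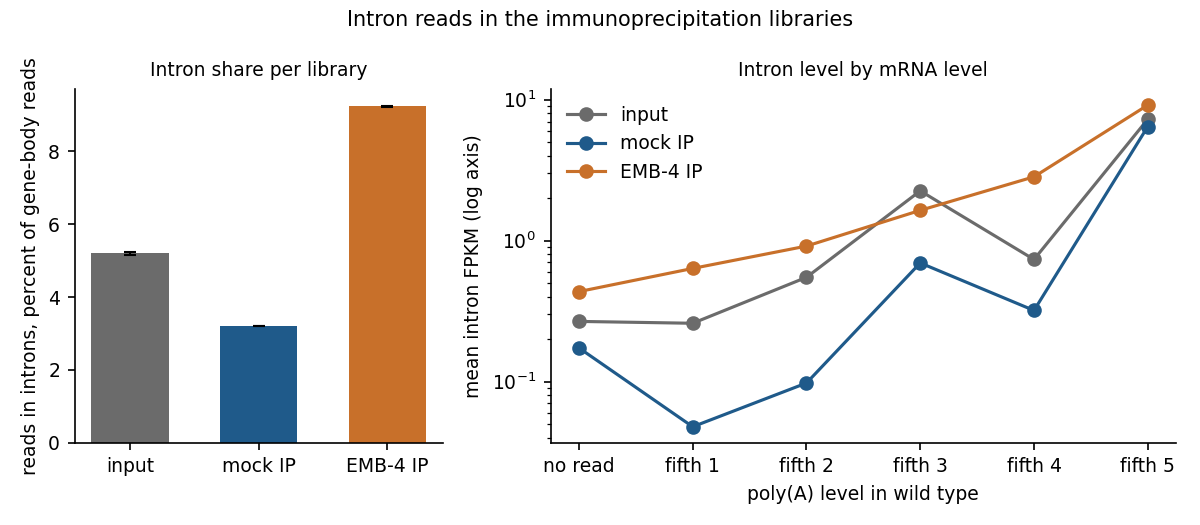
Left, share of gene-body reads in introns per library, with exact 95% binomial intervals for counting error. Right, mean intron FPKM (log axis) over classes of wild-type poly(A) level: from genes with no poly(A) read to the highest class it went from 0.435 to 9.16 in the EMB-4 precipitate, from 0.173 to 6.45 in the mock and from 0.267 to 7.27 in the input. The medians went from 0 to 2.74, from 0 to 0 and from 0 to 0.0717.

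Of 4901 genes with at least 30 intron reads, 3683 (75.1%) had at least 2 times as many intron reads as both controls after scaling to all gene-body reads, and the median ratios were 10.6 to the mock and 3.41 to the input. Most intron reads came from the precipitate (1434827, against 288984 in the mock and 123242 in the input), so the requirement of 30 reads favoured genes high in it. The median ratios exceed those of the whole libraries. Part of that gap may lie with a few genes, since the whole-library ratio to the mock was 5.88 without the 10 genes with most intron reads. The reasons were not separated. For 3608 of the listed genes the interval to the mock lay above 2, for 2269 the intervals to both did, and 1992 had fewer than 3 intron reads in the mock. Only 126 tested genes had a ratio to the mock below 1 and 14 had both ratios at or below 0.5. Ordered by the lower bound of the ratio to the mock, icd-1 and the transcription factor gene ets-4 came first. The gene icd-1, coding for a subunit of the nascent polypeptide-associated complex, had 780 intron reads in the precipitate, 0 in the mock and 12 in the input. Against a floor of 3 reads it was 151-fold over the mock (exact interval from 122), and it was 9.92-fold over the input. For ets-4 the reads were 4065, 12 and 87 (196-fold over the mock, interval 112 to 380). Others were the acyl-CoA dehydrogenase gene acdh-2 (165-fold over the mock), the splicing factor gene teg-4 (174), W07E11.1 (233) and phaf-1 (167). A rise of the whole transcript also raises these ratios. Introns of ets-4 held 4065 of 12228 gene-body reads in the precipitate and 87 of 266 in the input, and those of acdh-2 6840 of 13599 and 192 of 315. These 2 genes thus showed no clear excess of intron share over the input. The other named genes did, except pin-2. The hexokinase gene hxk-1, cpna-1 and Y62E10A.20 had 0 intron reads in the mock. Against the same floor they were 92.8-fold, 114-fold and 103-fold higher (exact intervals from 75.1, 92.6 and 83.6). In pin-2 (100.1-fold over the mock, 2.42-fold over the input) introns held 523 of 537 gene-body reads of the input, and reads of another transcript at that place were not excluded. Intron reads of emb-4 itself numbered 852, 80 and 17 (6.17-fold over the mock, interval 4.91 to 7.87, and 7.65-fold over the input, interval 4.75 to 13.2).

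By list, 17 of 37 ribosomal protein genes with enough intron reads were listed, and their median ratios lay at the 3.8 percentile of matched random lists for the mock and 0.3 for the input. Oocyte genes had 6 of 13 listed (7.9 and 1.8 percentile) and collagens 1 of 6 (0.0 and 2.3). Sex determination genes had 11 of 12 listed (82.9 and 67.1 percentile), innate effectors 5 of 5 (69.8 and 66.7) and intestine genes 9 of 10 (68.6 and 70.7). Argonautes had 10 of 11 listed, small RNA biogenesis genes 12 of 17, nuclear RNAi genes 10 of 13, P granule genes 7 of 12, spliceosome genes 16 of 23 and meiosis genes 11 of 13. Other counts were muscle (13 of 20), neuron (4 of 9), heat shock (10 of 15), C-type lectin (11 of 17), F-box (19 of 35), MATH and BATH (10 of 16), ERGO-1 target (2 of 6), vitellogenin (3 of 4), spermatogenesis (3 of 3) and pals genes (2 of 2), with 0 of 1 major sperm protein genes, 0 of 1 microRNAs and 0 histone genes with enough reads. In the mutant, the 3507 tested genes of the EMB-4 intron list had a poly(A) median of -0.17 (823 rises, 1261 falls, camera adjusted p = 0.0948) and an rRNA-depleted median of -0.18 (901 rises, 1344 falls, camera adjusted p = 0.0755). Under library totals the list passed as lower than other genes in both (adjusted p = 0.0184 and 0.0141), and the lowest adjusted p with 1 library left out were 0.0409 and 0.0452. With an estimated correlation it had adjusted p = 0.523 and 0.54. In small RNA 1695 of 2655 fell and 152 rose (median -0.80, camera adjusted p = 0.00953, adjusted p = 0.663 with an estimated correlation).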

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

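Chosen after the results were seen were the tests of germline tissue other than sperm, of sampling stage, of scaling in mRNA and small RNA, of ribosomal protein genes and of genomic DNA, of which the median was chosen after the mean was seen. The other tests were written before their results were seen.

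The genotype change differed between rRNA-depleted and poly(A) RNA, by the interaction term of the fit, for 12 genes. For histone genes the differences in log2 were -3.70 (his-14), -3.25 (his-10), -2.77 (his-26), -2.09 (his-43), -1.93 (his-12), -1.65 (his-25), -1.41 (his-50) and -1.35 (his-28). For the others they were -1.50 (acs-2), 1.39 (Y16B4A.2), 1.43 (bcf-1) and 1.66 (gfi-1). The histone genes are close copies of each other, so which copy the reads came from is uncertain. Only his-14 and his-10 held without each library in turn. Besides his-74, histone genes called lower in rRNA-depleted RNA had the sequence-name prefix ZK131 or F08G2. The ZK131 genes, his-9 to his-16, his-25 and his-26, changed by -0.96 to -2.25, and the F08G2 genes, his-42 to his-44, by -1.13 to -1.82. The gene his-74 changed by -1.63, and by -1.67 in poly(A) RNA. The genes his-50 (0.11) and his-28 (0.34) did not pass in rRNA-depleted RNA and rose in poly(A) RNA. With edgeR his-12 had an adjusted p of 0.131, and under library totals his-25 had 0.0509. No explanation of these differences was tested.

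The germline lists fell and somatic lists rose in the mutant mRNA. For an equal loss of all germline tissue, sperm included, a limit of 0.5 log2 between list medians was set beforehand. The medians of the 4 germline lists spanned 1.30 log2 (interval 1.08 to 1.59). That span came from the spermatogenesis list alone. Only 29 of its 44 members passed the filter, 22 of these were not called, and the log2 scale understates the change of low genes. The span therefore does not decide whether sperm was included in a loss. The oocyte, meiosis and P granule medians spanned 0.24 (0.0617 to 0.439), as a lower share of germline tissue other than sperm would give. A younger sampling stage would lower yolk genes, and the vitellogenin median was 0.996 (members from 0.716 to 1.73), or 0.49 under library totals. This does not decide the stage. The values are relative to libraries in which germline genes fell, and the other somatic lists rose as well. Scaling is unlikely to account for the oocyte, meiosis and P granule falls (median at most -1.44, -1.57 to -1.31, under each scaling tried). The neuron median stayed above 0 under each of them (at least 0.426, 0.288 to 0.849). All these scalings are relative, so a neuron rise and a smaller germline share cannot be told apart. For muscle and intestine scaling and a rise cannot be told apart either (muscle 0.186, -0.051 to 0.384, under library totals). An effect of the genotype itself stays open as untested.

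Small RNA reads fell for most called genes. An effect of depth could not be decided. The deeper pair gave a lower median than the shallower pair by -0.255 (-0.281 to -0.235), and both lay below 0 (-0.819 and -0.564). The mutant library was the deeper in both pairs (22121247 against 9355454 and 1512635 against 1051505 total reads). The pairs therefore do not separate depth from genotype. For the fall over all genes, scaling and a loss of small RNA cannot be told apart: the median was -0.354 (-0.375 to -0.335) with library totals, and TMM and median-ratio factors centre the genes, which fixes their outcome. Loss of target transcripts and a separate effect on small RNA cannot be told apart either: genes lower in poly(A) RNA had a median lower by -0.201 (-0.242 to -0.159) than genes not called. For ribosomal protein genes a general fall of their poly(A) transcripts is unlikely as the cause. Their small RNA median was at most -0.932 (-1.08 to -0.76) under any scaling while their poly(A) median was above 0. In rRNA-depleted RNA their median was 0.52, or 0.00 under library totals. The RNA was not divided by tissue, so fewer transcripts in germline tissue alone stay possible. An effect of the genotype itself stays open as untested.

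Introns held a larger share of reads in the EMB-4 precipitate than in the mock and input. DNA would add like intron density to genes with and without mRNA. For the typical gene DNA is unlikely as the source: over genes with at least 500 nt of introns the median density above the input in the highest class of poly(A) level, less 3 times that in genes with no poly(A) read, was 1.87 FPKM (1.77 to 1.96), and 2.02 (1.93 to 2.12) above the mock. By the mean, which a few genes can dominate, DNA and bound RNA cannot be told apart (1.39, -0.271 to 2.85, above the input and 1.93, 0.0301 to 3.64, above the mock). A few genes did not make the excess, since the ratio to the mock was 5.88 without the 10 genes with most intron reads. With 1 library of each kind, a difference between these single libraries stays open, and binding of unspliced RNA by EMB-4 was not tested against it.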

How the results depend on the processing

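Most alternatives were planned before the data were examined. Chosen after were edgeR, TMM, other pseudocounts, list tests under other scalings or without a library, and the intron share over all recovered genes. Total numbers of calls not listed moved by less than 1.5 times. Among small RNA genes called in both, 2 changed direction with median-ratio factors and 3 with edgeR, and the share of rises went from 14.3% to 54.5% with TMM. Where a cause is not stated, the cause was not tested.

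Requiring a log2 change of at least 1 left 3888 of 6905 poly(A) calls, 4571 of 7464 rRNA-depleted calls and 3204 of 5426 small RNA calls. DESeq2 called 6743, 5849 and 2181, and edgeR 8519, 6855 and 4778. Fitted alone, the poly(A) libraries gave 8815 calls and the rRNA-depleted libraries 6089, against 6905 and 7464 in the shared fit. Calls in rRNA-depleted RNA that rest on the shared spread are therefore less certain. Small RNA calls fell to 3408 with TMM. Small RNA rises, 778 at first, were 1234 with DESeq2 (947 falls), 2609 with edgeR (2169 falls), and 339, 314 and 1181 without mutant replicate 1, mutant replicate 2 and wild-type replicate 2. Leaving out each library gave 5022 to 5241, 6557 to 7402 and 3451 to 5380 calls. The lowest small RNA numbers, 3451 and 3615, came without mutant replicate 1 and without mutant replicate 2.

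The 12 genes whose genotype change differed between library types were the least stable result. They became 4 with no filter, 25 with DESeq2, 14 with edgeR and 6 with a smaller pseudocount. Leaving out each library gave 2 to 68 genes: 68 without rRNA-depleted wild-type replicate 1, 2 without either mutant poly(A) library, 4 and 3 without wild-type poly(A) replicate 1 and 2, and 5 and 4 without rRNA-depleted mutant replicate 1 and 2.

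The block for replicate number gave 3 such genes, and a block for a culture shared by both library types gave 16. With the replicate block the 3 genotype comparisons gave 6435, 7072 and 5384 calls. Libraries with the same number did not deviate together (correlations -0.096 to 0.086), so the numbers were not treated as pairs.

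List calls fell from 25 to 2 in poly(A) RNA, from 24 to 2 in rRNA-depleted RNA, from 6 to 0 for the library type difference and from 13 to 0 in small RNA when camera estimated the correlation. With fry, which tests against no change and not against other genes, they were 29, 29, 0 and 19; the 19 were all lower, 8 of them among the 13, and 0 of the 5 lists that camera placed higher passed. Without each library, the lists of the library type difference numbered 2 to 10: 3 without mutant poly(A) replicate 1, 2 without rRNA-depleted mutant replicate 2 and 10 without rRNA-depleted wild-type replicate 1.

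Without the 10 genes with most intron reads, the intron share ratio of the EMB-4 precipitate moved from 2.88 to 5.88 over the mock and from 1.78 to 2.39 over the input. Over all recovered genes it was 2.45 and 1.75. The list of 3683 genes with raised intron reads became 2017 with at least 100 intron reads and 2051 with a ratio of at least 4.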

Other observations

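Both questions below were written before their results were seen, and the genes in the next paragraph were chosen after their values were seen.

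A group of 17 genes had no read in any of the 4 mutant mRNA libraries and at least 5 normalised reads in both wild-type poly(A) libraries. The reverse held for 1 gene. Among the 17 were try-8, of the trypsin-like family, at 30.9 and 29.3 in wild-type poly(A) RNA and 14.4 and 30.2 in wild-type rRNA-depleted RNA, and F26D2.16, at 28.5 and 18.4 in poly(A) RNA. Others were C-type lectin genes: clec-219 (24.6 and 21.8 in poly(A) RNA), clec-207 (19.8 and 13.0) and clec-96 (9.18 and 8.51). The metalloprotease gene nas-17 (8.70 and 7.98) was also among them.

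Among the most abundant genes of the mutant poly(A) libraries, the yolk gene vit-2 held 4.96% of reads against 2.14% in the wild type, and the aspartic protease genes asp-1 and asp-6 held 3.01% against 2.05% and 2.68% against 1.29%. Another abundant protease gene, cpr-9, did not pass (log2 change 0.03, limma adjusted p = 0.866). The variant histone gene his-71 changed alike in both library types (1.53 and 1.47), as did his-37 (1.32 and 1.21) and his-19 (0.94 and 0.88).

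These 17 genes were tested for lying together in the genome, as with a deletion. Among the 17 genes 0 pairs were neighbours, against a mean of 0.0196 in 10000 random lists, so the test gave no sign of a shared deletion. The test detects only neighbours, and losses at separate places stay open.

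Intron length was asked because EMB-4 is described as binding introns. Across 10713 genes (87.6% of those tested) its Spearman correlation with the poly(A) change was 0.0251 (0.00636 to 0.0437) and with the rRNA-depleted change 0.019, inside the limit of 0.1 set beforehand. Genes are not independent replicates, and intron lengths came from a gene table of another build. A steady trend of signed change with total intron length was therefore unlikely to account for the mRNA changes. Larger changes in both directions, or a relation that is not steady, would escape this correlation and stay open. From the shortest to the longest quintile of intron length, the median poly(A) changes were -0.15, -0.19, 0.09, 0.08 and -0.02. The number or the retention of introns was not analysed here.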
